A study of Arabidopsis thaliana with 28 samples.

How the data were processed

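Rosettes of 3-week-old Arabidopsis thaliana plants of the accessions Bla-2 and Kon were profiled on 28 single-colour, biotin-labelled expression arrays. Some plants stayed free of mites. Others received 10 adult females of the spider mite Tetranychus urticae and were taken after 1 h, 3 h, 6 h, 12 h and finally 24 h. A dense cover of mites for 1 h made the third treatment, called feeding site in the labels. Each of the 14 groups, 7 per accession, held 2 arrays made from pools of 6 plants. The labels call the arrays of a group biological replicates, whereas the extraction protocol speaks of RNA processed in duplicate from pooled plants. The p-values therefore measure the spread between these arrays, which may be partly technical. Each accession had 1 control group, titled 24 h, and the labels give no separate control for the earlier times.

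The deposited values were log2 expression values summarised and normalized by the authors with RMA, per the submitters' processing notes. The version, the array type and the probe set definition are not given in the sources used here. The table held 21428 probe sets with 1 probe set per locus code, of which 21348 were nuclear, 77 mitochondrial and 3 chloroplast loci. No value was missing, and values ran from 1.72 to 13.5. Of the loci, 21231 matched the TAIR10.1 gene table used for names, and 9006 of all probe sets had a symbol other than the locus code. Coordinates are not given because the genome build behind the probe sets is unknown. Several list genes had no probe set among the values used, so 265 of 307 list entries were measured.

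Array medians lay between 5.45 and 5.58 on the log2 scale. The 2 arrays of a group correlated across probe sets at r = 0.991 to 0.998, and the SD of their log2 difference ran from 0.151 to 0.303. The highest r between any 2 arrays was 0.998, so none repeated another. Level differences between genes raise these r. With genes centred within the accession, partners in control plants correlated at 0.85 in Bla-2 and 0.77 in Kon. In Kon they correlated at 0.21, 0.11, 0.01 and 0.25 at 1, 3, 6 and 12 h, and in Bla-2 at 0.02 at 12 h. The other pairs lay between 0.35 and 0.6. By this measure 11 of the 28 arrays were nearest to an array of another group. The number of arrays limits the precision. Raw scanner signals were not used here, and signal over background was not computed.

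A linear model with 1 coefficient per group was fitted to all 28 arrays with limma 3.58.1 in R 4.3.3, and empirical Bayes moderation was applied without trend. The fit had 14 residual degrees of freedom and a prior of 6.47. Benjamini-Hochberg adjustment ran over all probe sets within each comparison, and a gene was called at an adjusted p under 0.05. Time courses were tested with an F-test over the 5 time points. Differences in response were tested as interactions. All p-values are two-sided. A total of 24 gene lists were tested with camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 24 lists of a comparison. The same test was repeated with an estimated correlation. A fry test was also run and is not reported. Of 456 list tests, 214 passed the threshold with the preset correlation and 107 of them with an estimated one.

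The gene lists, the design, the alternatives named here and the rule for named genes were written before the data were examined. The rule took the 6 highest and 6 lowest log2 fold changes for the feeding site, 24 h and control comparisons, and the 2 highest and 2 lowest for the other time points, among called genes whose arrays did not overlap between the groups. For the accession differences in response at the feeding site and 24 h it took the 6 highest and 6 lowest called genes. For each list described it added up to 4 members with the smallest p, and a gene named once could be given in any comparison. The few genes named outside this rule are marked in the text as chosen after their values were seen. The comparison of 24 h with 1 h was added after the data had been seen, as were fits without the 1 h arrays and without 2 deviating 12 h arrays. The other alternatives were a further quantile normalization, centring of each array, a filter on dim probe sets, a trended and robust variance, separate fits per accession, a replicate block, a 2-fold minimum and leaving out each array in turn. The procedure was tested on simulated data of 21428 probe sets with 200 changed genes. Noise was normal and independent, with 1 SD per gene on all arrays, and genes changed only in the Bla-2 feeding site group. The real groups differ in spread, so the rates may not carry over to them. For feeding site against control in Bla-2 it recovered 34% of genes changed by 0.5 on the log2 scale, 96% at 1, 98% at 2 and 100% at 4, with 12 false calls. For the accession difference in the feeding site response the shares were 10%, 66%, 96% and 100%, with 8 false calls.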

Results

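Gene expression was measured in whole rosettes of 2 Arabidopsis accessions, Bla-2 and Kon, with and without spider mites. Values are RMA-normalized log2 expression, fold changes are on the log2 scale with their standard error (SE), and group levels are means ± SD of n = 2 arrays. The first principal component, with 38.0% of the variance, separated the accessions. The second, with 15.9%, separated control plants from the groups with mites in both accessions.

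The feeding site treatment, a dense cover of mites for 1 h, was compared with control plants to describe the change under a dense attack. The control group was titled 24 h, so time of day or handling can enter this comparison too. In Bla-2 the highest increases were in JAZ7 (AT2G34600), a repressor of jasmonate signalling, at 5.58 (SE 0.6, adjusted p = 1.15e-06), and in WRKY40 (AT1G80840), a transcription factor, at 5.42 (SE 0.34, adjusted p = 7.24e-10). The lipoxygenases LOX4 (AT1G72520) and LOX3 (AT1G17420) of jasmonate synthesis rose by 5.27 and 5.18, AT2G22880 by 5.31 and JAZ5 (AT1G17380) by 4.8. In Kon the highest were TAT3 (AT2G24850), a jasmonate-responsive aminotransferase, at 5.82 (SE 0.26, adjusted p = 4.94e-12), LOX3 at 5.6, JAZ7 at 5.29, WRKY40 at 5.22, the allene oxide cyclase AOC3 (AT3G25780) at 5.05 and JAZ5 at 5.02. JAZ7 stood at 3 ± 0.02 in Bla-2 control plants and 8.58 ± 0.35 at the feeding site, and at 3.11 ± 0.08 and 8.4 ± 0.18 in Kon. The strongest decreases were smaller. XTH31 (AT3G44990), a cell wall xyloglucan enzyme, changed by -1.85 in Bla-2 and -1.5 in Kon, AT5G57760 by -1.42 and -1.75, and AT5G48490 by -1.5 and -1.82. Further decreases in Bla-2 were AT2G27420 at -1.65, RR16 (AT2G40670) at -1.53 and ETC2 (AT2G30420) at -1.41. In Kon they were AT5G02760 at -1.64, SAUR63 (AT1G29440) at -1.56 and the expansin EXPA8 (AT2G40610) at -1.47.

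At the feeding site, of 20 measured JAZ repressors and jasmonate turnover genes, 16 were higher and 0 lower in each accession, with a list median of 3.38 in Bla-2 and 3.02 in Kon. JAZ10 (AT5G13220) rose by 4.48 and 4.71, and AT5G05600, a jasmonate oxidase, by 3.84 and 4.06. In jasmonate biosynthesis 8 of 15 genes in Bla-2 and 9 in Kon were higher, among them AOC3 at 4.59 and 5.05 and OPR3 (AT2G06050) at 2.28 and 2.56. In the MYC2 branch 4 of 9 genes in Bla-2 and 8 in Kon were higher, with MYC2 (AT1G32640) itself at 2.6 and 3.42. Of 27 early wound and calcium response genes, 18 were higher and 1 lower in Bla-2, and 17 higher in Kon. MYB15 (AT3G23250) rose by 4.48 and 4.52 and the calmodulin-like CML37 (AT5G42380) by 2.57 and 2.76. Indole glucosinolate genes, which make tryptophan-derived defence compounds, were higher for 13 of 19 in Bla-2 and 10 in Kon, with CYP83B1 (AT4G31500) at 1.39 and 1.69 and SOT16 (AT1G74100) at 1.12 and 1.38. These 5 lists passed the camera test in both accessions also with an estimated correlation, at adjusted p between 0.000506 and 0.0238. Adjusted over the list alone, 16 JAZ and turnover genes were higher in each accession, 9 and 10 jasmonate biosynthesis genes, 6 and 8 of the MYC2 branch, 20 and 18 wound and calcium genes and 15 and 12 indole glucosinolate genes.

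Abscisic acid and dehydration genes were higher at the feeding site for 6 of 13 in each accession, with RD26 (AT4G27410) at 2.81 and 2.61, but this list missed the threshold with an estimated correlation, at adjusted p = 0.073 in Bla-2 and 0.153 in Kon. In the salicylate list 3 of 15 genes were higher and 2 lower in Bla-2, and 2 higher and 1 lower in Kon. EDS5 (AT4G39030), a salicylate transporter, rose by 1.28 and 2.07, and NIMIN1 (AT1G02450) changed by -1.2 and -1.21. The call for this list was lost with an estimated correlation, at adjusted p = 0.476 in Bla-2 and 0.206 in Kon. Tryptophan biosynthesis had 2 of 4 genes higher in each accession, with the anthranilate synthase subunit ASA1 (AT5G05730) at 1.28 and 1.12. That list's adjusted p with an estimated correlation was 0.135 and 0.107. Leaf volatile genes were higher for 1 of 6 in Bla-2 and 3 in Kon. The geranyllinalool synthase gene TPS04 (AT1G61120) rose by 3.53 and 4.41, and the list's adjusted p with an estimated correlation was 0.434 in Bla-2 and 0.023 in Kon. Camalexin genes were higher for 2 of 4 in Bla-2 and 1 in Kon, with PAD3 (AT3G26830) at 1.18 and 2.25, and adjusted p with an estimated correlation was 0.323 and 0.306. Among glucosinolate breakdown genes 2 of 7 were higher in Bla-2 and 1 in Kon, with MVP1 (AT1G54030) at 0.75 and 1.18. In the ethylene and jasmonate branch ERF1 (AT3G23240) rose by 0.5 and 0.77, 1 of 8 genes in each accession. With limma 0 of 17 photosynthesis genes were called in either accession, and 0 had an unadjusted p under 0.05. Of 14 clock genes 0 were called, and at an unadjusted p under 0.05 there were 0 in Bla-2 and 1 in Kon. Of 7 root markers and 9 vascular markers limma called 0 in either accession, and at an unadjusted p under 0.05 there were 1 and 0 in each. Among flowering and shoot meristem markers AGL8 (AT5G60910) fell by 0.46 in Bla-2, and among guard cell markers MYB60 (AT1G08810) fell by 0.62 in Kon.

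In total 2618 of 21428 genes differed between feeding site and control in Bla-2, 1209 higher and 1409 lower. In Kon 1457 differed, 1006 higher and 451 lower. The share of higher genes in Bla-2 turned with the scaling, from 46.18% to 52.95% with arrays centred on their medians and 51.89% with renewed quantile normalization, and it was 38.93% with the accessions fitted apart and 40.11% without dim probe sets. Changes of at least 2-fold were mostly increases, with 512 higher and 53 lower in Bla-2 and 501 and 38 in Kon. The number in Bla-2 was 1046 without feeding site replicate 1, 1062 without control replicate 1 and 1173 without control replicate 2. In Kon it was 763, 847 and 876 without the corresponding arrays.

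**Figure D1:**
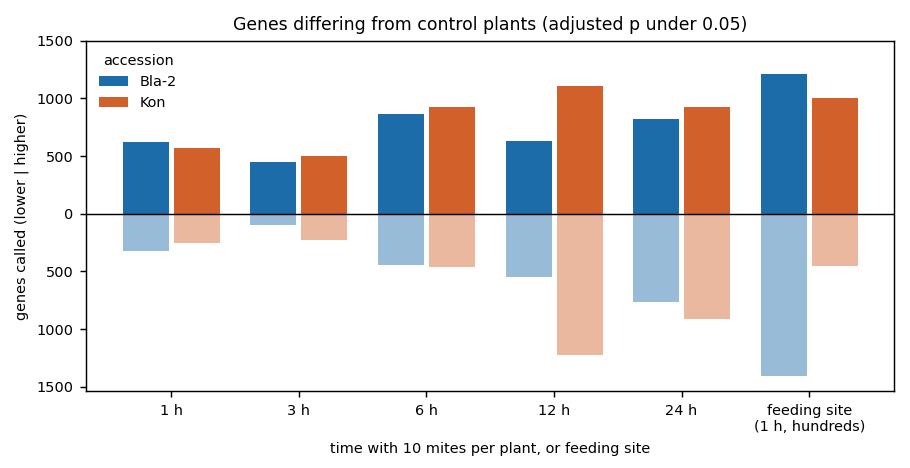
Number of genes differing from control plants at adjusted p under 0.05 for each time with 10 mites and for the feeding site, in Bla-2 (blue) and Kon (orange), with full-colour bars upwards for higher genes and pale bars downwards for lower genes. At the feeding site 1209 genes were higher in Bla-2 and 1006 in Kon.

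The feeding site responses of the accessions were largely shared in direction. Of the called genes, 800 were higher in both accessions, where independent lists would share 56.8, and 255 were lower in both, against 29.7. By limma 0 genes were called in opposite directions, and fold changes correlated across genes at r = 0.84, where genes are not independent replicates. The accessions have separate controls. The shared calls numbered 1055 in all, 633 without Kon feeding site replicate 1 and 679 without Kon control replicate 2.

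**Figure D2:**
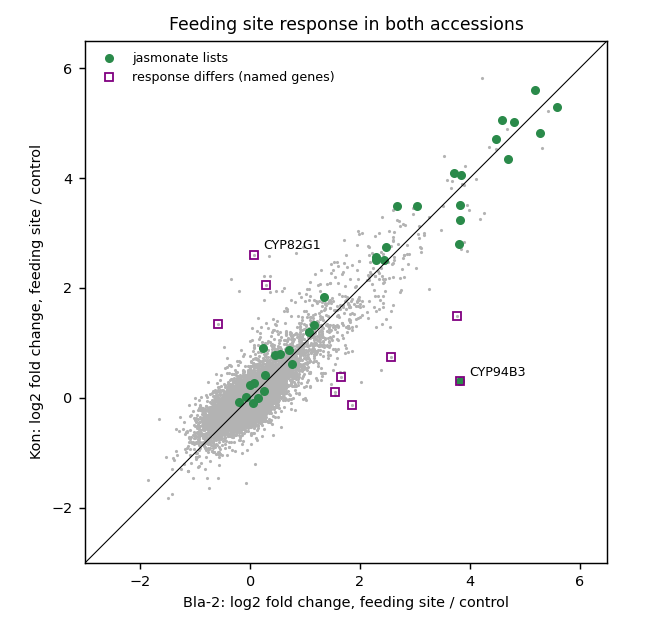
Log2 fold change of feeding site against control for each gene in Bla-2 (horizontal) and Kon (vertical), with the line of equal response. Green points are the jasmonate biosynthesis and the JAZ and turnover lists, with JAZ7 at 5.58 and 5.29, and open squares mark named genes whose response differed between accessions, such as CYP82G1 at 0.08 in Bla-2 and 2.6 in Kon.

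The time course, 10 mites per plant for 1 to 24 h, was compared with control to follow the response to light infestation. At 1 h the highest genes were LOX3 (AT1G17420) at 4.36 and LOX4 (AT1G72520) at 4.34 in Bla-2, and TAT3 (AT2G24850) at 5.35 and LOX3 at 4.46 in Kon. At 3, 6 and 12 h AT1G54020 was among the 2 highest in both accessions. It rose by 4.37 at 3 h, 5.64 at 6 h and 5.28 at 12 h in Bla-2, and by 5.33, 6.21 and 6.65 in Kon. TAT3 led in Kon at 3, 6 and 12 h, with 6.14, 6.86 and 6.93, and rose by 4.27 at 3 h in Bla-2. NATA1 (AT2G39030), an acetyltransferase that makes the defence metabolite acetylornithine, rose by 5.45 at both 6 and 12 h in Bla-2. The gibberellin-regulated GASA6 (AT1G74670) was among the lowest in Bla-2 at 3, 6 and 12 h, with -2.17, -1.92 and -1.8, and in Kon at 6 and 12 h, with -2.42 and -2.28. AT5G24210 at -1.66 and AT4G33666 at -1.61 were lowest at 1 h in Bla-2, and BT2 (AT3G48360) at -2.82 and AT1G49500 at -2.23 in Kon. AT5G57760 changed by -1.77 at 3 h in Bla-2 and by -1.88 in Kon, where GRP23 (AT2G32690) changed by -1.84. AT5G48490 changed by -1.76 at 6 h in Bla-2, and by -2.52 at 6 h and -2.23 at 12 h in Kon.

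After 24 h the highest genes in Bla-2 were AT1G54020 at 5.56 (SE 0.56), NATA1 (AT2G39030) at 5.5, the thionin THI2.1 (AT1G72260) at 5.07, the defensin PDF1.2 (AT5G44420) at 5.05, TAT3 (AT2G24850) at 4.53 and the trypsin inhibitor TI1 (AT2G43510) at 4.03. In Kon they were TAT3 at 6.63 (SE 0.26), PDF1.2 at 6.31, AT1G54020 at 6.25, NATA1 at 6.16, THI2.1 at 4.95 and the jacalin-type lectin JAL23 (AT2G39330) at 4.49. PDF1.2 stood at 2.69 ± 0.18 in control and 7.74 ± 0.09 at 24 h in Bla-2, and at 3.75 ± 1.6 and 10.06 ± 0.08 in Kon. Decreases at 24 h in Bla-2 were led by AT5G57760 at -1.94, the aldolase FBA5 (AT4G26530) at -1.92, SAUR23 (AT5G18060) at -1.67, RCI2B (AT3G05890) at -1.63, AT5G48490 at -1.62 and AGL87 (AT1G22590) at -1.6. In Kon they were AT5G48490 at -1.93, AT5G57760 at -1.86, the light-harvesting gene LHCB2.3 (AT3G27690) at -1.81, SAUR68 (AT1G29510) at -1.67, AT3G53250 at -1.65 and MES18 (AT5G58310) at -1.57.

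The JAZ and turnover list stayed high throughout, with between 14 and 18 of 20 genes higher at each time in either accession. Its median was 2.72 at 1 h and 1.46 at 24 h in Bla-2, and 2.09 and 1.72 in Kon. The 4 measured tryptophan biosynthesis genes were all higher from 3 h on in both accessions, with TRP1 (AT5G17990) at 1.5 at 6 h in Bla-2 and 1.46 in Kon. Indole glucosinolate genes were higher for between 9 and 13 of 19 at each time, with 1 lower at 3 and 6 h in Kon, and the methyltransferase IGMT5 (AT1G76790) rose by 2.24 and 2.65 at 6 h. These 3 lists passed with an estimated correlation at every time except tryptophan biosynthesis at 1 h, where adjusted p was 0.0831 in Bla-2 and 0.37 in Kon. Anthocyanin and flavonol genes were higher at 6 h for 8 of 13 in Bla-2 and 9 in Kon, with TT7 (AT5G07990) at 1.34 and 1.33 and the regulator PAP1 (AT1G56650) at 1.94 and 1.45. Adjusted p with an estimated correlation was 0.0335 and 0.0292. At 24 h 2 of these genes were higher in Bla-2, where adjusted p with an estimated correlation was 0.323, and in Kon the flavonol synthase FLS1 (AT5G08640) fell by 0.8.

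The salicylate list had 1 gene higher and 2 lower at 1 h in each accession, and by 24 h 7 of 15 were higher in Bla-2 and 10 in Kon. The glucanase BGL2 (AT3G57260) rose by 3.11 and 2.37 at 24 h, and PR5 (AT1G75040) by 2.13 and 3.06. Adjusted p with an estimated correlation at 24 h was 0.0246 and 0.00691. In the camalexin list 2 of 4 genes were higher at 24 h in both accessions. PAD3 (AT3G26830), which completes camalexin synthesis, rose by 2.37 and 4.03 and CYP71A13 (AT2G30770) by 2.47 and 3.18, with adjusted p = 0.0334 and 0.0121 for the list with an estimated correlation. In the ethylene and jasmonate branch 2 of 8 genes were higher and 1 lower in Bla-2 at 24 h, and 4 higher in Kon, with adjusted p = 0.0475 and 0.00691 with an estimated correlation. PDF1.2 (AT5G44420) was among them, and PR4 (AT3G04720) rose by 1.19 and 2.21. Among auxin response and expansin genes 5 of 12 were lower in Bla-2 at 24 h and 3 in Kon, with IAA29 (AT4G32280) at -1.38 and -1.19. That list's adjusted p with an estimated correlation was 0.074 and 0.262. Protease inhibitor genes were higher for 2 of 8, TI1 and KTI1 (AT1G73260), and aliphatic glucosinolate genes for 1 of 18 in Bla-2 and 0 in Kon. With an estimated correlation adjusted p was 0.117 and 0.263 for the inhibitors, and 0.231 and 0.816 for the aliphatic glucosinolate genes. Of the photosynthesis list 2 of 17 genes were lower at 24 h in Bla-2, LHCB3 (AT5G54270) at -0.41 and LHCA4 (AT3G47470) at -0.35, with adjusted p = 0.291 for the list with an estimated correlation. Limma called 0 of 14 clock genes at 24 h, where 0 in Bla-2 and 3 in Kon had an unadjusted p under 0.05. In Bla-2 the mean of the day and evening clock list was 8.31 and 8.4 on the control arrays. It was 8.35 and 8.19 at 1 h, 8.12 and 8.11 at 3 h, 8.29 and 8.25 at 6 h, and 7.93 and 8.23 at 12 h. In Kon it was 8.14 and 8.3 in control, 8.03 and 8.05 at 1 h, and 7.99 and 7.76 at 3 h. Later it was 8.18 and 8.1 at 6 h, and 7.98 and 8.05 at 12 h. The list joins clock genes of the day and of the evening, which another harvest time can move in opposite directions, so its mean can stay level. Called clock genes at 1 to 12 h and the morning list are not given here. Time of day can enter these comparisons.

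Heat shock genes were high at 1 h of 10 mites. In Bla-2 6 of 8 were higher, with a list median of 2.37, and in Kon 5 of 8, with a median of 1.85. HSFA2 (AT2G26150), a heat shock factor, rose by 3.27 and 2.55, and HSP70 (AT3G12580) by 2.75 and 3.16. Adjusted p with an estimated correlation was 0.00201 and 0.0105. At 6 h 2 of 8 were higher in Bla-2 and 4 in Kon, with adjusted p = 0.0663 and 0.0175 with an estimated correlation. At 24 h 3 were higher in Kon, among them HSP70 at 1.75, with adjusted p = 0.125 with an estimated correlation. The labels give 1 control group per accession, titled 24 h, and none for 1 h.

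**Figure D3:**
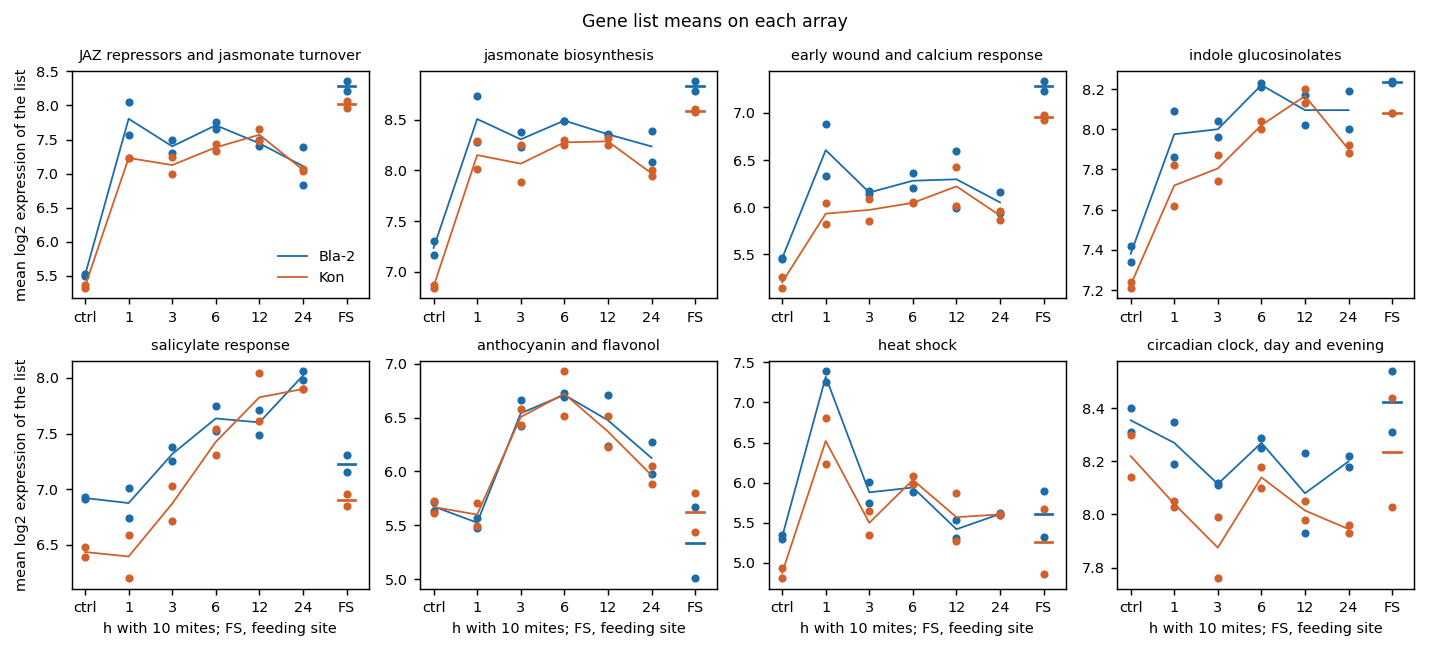
Mean log2 expression of 8 gene lists on each array (points) in control plants, after 1 to 24 h with 10 mites and at the feeding site (FS), with lines through group means for Bla-2 (blue) and Kon (orange). Vertical scales differ between panels. The heat shock list mean was 7.25 and 7.39 on the Bla-2 arrays of 1 h and 5.9 or lower on the feeding site arrays.

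By the F-test over 5 times 1796 genes changed in Bla-2 and 2736 in Kon. The genes called in Bla-2 at 1, 3, 6, 12 and 24 h numbered 941, 550, 1315, 1177 and 1589, and in Kon 823, 729, 1385, 2330 and 1832. At 24 h 822 were higher and 767 lower in Bla-2, and 923 higher and 909 lower in Kon. Changes of at least 2-fold at 24 h were mostly increases, with 245 higher and 54 lower in Bla-2 and 361 and 74 in Kon. With arrays centred on their medians, the share of higher genes at 24 h was 39.61% in place of 51.73% in Bla-2 and 49.16% in place of 50.38% in Kon, and at 12 h 49.55% in place of 53.78% in Bla-2 and 51.49% in place of 47.38% in Kon. With the accessions fitted apart the F-test called 2747 genes in Bla-2 and 1228 in Kon, so the order of the accessions turned. It also turned at 3 h, with 693 and 440, at 6 h, with 1879 and 817, at 12 h, with 1877 and 1471, and at 24 h, with 2567 and 1047. In these fits the share of higher genes in Bla-2 and Kon was 48.53% and 58.74% at 12 h, and 48.77% and 62.18% at 24 h. The Bla-2 F-test count was 991 without control replicate 1 and 1023 without control replicate 2. The counts at 24 h without 24 h replicate 1, 24 h replicate 2, control replicate 1 and control replicate 2 were 406, 804, 479 and 519 in Bla-2 and 858, 1131, 1115 and 753 in Kon. At 1 h, without 1 h replicates 1 and 2 and control replicates 1 and 2 in this order, they were 307, 1189, 382 and 402 in Bla-2 and 1491, 325, 366 and 334 in Kon. In the same order, at 3 h they were 319, 239, 259 and 281 in Bla-2 and 376, 755, 330 and 381 in Kon. At 6 h they were 721, 639, 637 and 644 in Bla-2 and 996, 1372, 733 and 713 in Kon. At 12 h they were 535, 832, 357 and 406 in Bla-2 and 1473, 1857, 1349 and 1185 in Kon. The 12 h replicates differed in a pattern shared by Bla-2 replicate 1 and Kon replicate 2, and without these 2 arrays, a setting chosen after the data had been seen, the 12 h counts were 613 and 1993.

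Dense and light attack of the same length were compared directly as feeding site against 1 h of 10 mites. HSPRO2 (AT2G40000) was higher at the feeding site by 2.25 in Bla-2 and 2.36 in Kon. Other genes higher in Bla-2 were AT1G15010 at 1.81, RAS1 (AT1G09950) at 1.77, AT3G02840 at 1.74, AT3G55840 at 1.73 and SRO5 (AT5G62520) at 1.72. In Kon they were AT1G05575 at 2.5, AT2G25735 at 2.4, JAZ8 (AT1G30135) at 2.22, BAP1 (AT3G61190) at 2.2 and AT3G01830 at 2.17. Early wound and calcium genes were higher for 4 of 27 in Bla-2 and 15 in Kon, with CML37 (AT5G42380) at 1.32 and 1.82, and adjusted p with an estimated correlation was 0.138 in Bla-2 and 0.00914 in Kon. Bla-2 1 h replicate 1 stood apart from its partner towards the feeding site. Its mean of the wound and calcium list was 6.88, against 6.33 in replicate 2, and it correlated at r = 0.53 with feeding site replicate 1 and 0.35 with its partner across genes. Whether the accessions differ in this comparison was not tested. JAZ and turnover genes were higher for 1 of 20 in Bla-2 and 7 in Kon, where JAZ8 was among them, with adjusted p = 0.223 and 0.00914 with an estimated correlation.

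Heat shock genes were lower at the feeding site than at 1 h for 6 of 8 in Bla-2 and 5 of 8 in Kon, with adjusted p = 0.00402 and 0.0174 with an estimated correlation. Members of this list of 8 made up 3 of the 6 strongest decreases in Bla-2 and 5 of 6 in Kon. Heat shock genes outside the list were not counted. HSFA2 (AT2G26150) changed by -2.58 and -2.18, HSP70 (AT3G12580) by -2.43 and -1.89 and HSP90.1 (AT5G52640) by -2.35 and -1.87. AT5G51440 at -2.68, AT5G48570 at -2.46 and AT1G71000 at -2.43 completed the lowest 6 in Bla-2, and MBF1C (AT3G24500) at -1.77, TIN1 (AT5G64510) at -1.76 and HSP101 (AT1G74310) at -1.5 in Kon. In total 213 genes differed in Bla-2, 128 higher and 85 lower, and 300 in Kon, 237 higher and 63 lower. With the accessions fitted apart the order turned, with 336 genes in Bla-2, 51.49% of them higher in place of 60.09%, and 206 in Kon. In Bla-2 the number was 350 without 1 h replicate 1, 28 without 1 h replicate 2 and 78 without feeding site replicate 1. In Kon it was 68 without 1 h replicate 2, 108 without feeding site replicate 1 and 91 without feeding site replicate 2.

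Control plants of the accessions were compared to describe their difference without mites. AT2G25510 was higher in Bla-2 by 8.19 (SE 0.32), PCC1 (AT3G22231) by 6.43, AT3G43740 by 4.97, XBCP3 (AT1G09850) by 4.67, CYP71B14 (AT5G25180) by 4.5 and AT3G47250 by 4.39. QQS (AT3G30720) was lower in Bla-2 at -6.98 (SE 0.41), the tubulin gene TUA6 (AT4G14960) at -5.88, AT2G15555 at -5.43, AT4G29200 at -5.17, AT5G45500 at -4.75 and AT2G32160 at -4.36. In the jasmonate biosynthesis list 6 of 15 genes were higher in Bla-2 and 2 lower, with ACX5 (AT2G35690) at 2.24 and AOC4 (AT1G13280) at -0.86. In the MYC2 branch 5 of 9 were higher, with JR1 (AT3G16470) at 1.38. The adjusted p of both lists was 0.627 with an estimated correlation. In all 1742 genes differed, 980 higher in Bla-2 and 762 lower. The number was 927 without Bla-2 control replicate 1, 896 without Bla-2 control replicate 2, 946 without Kon control replicate 1 and 1117 without Kon control replicate 2. Differences in sequence under the probes can enter these values.

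Whether the accessions respond differently was tested by interaction. At the feeding site 10 genes differed in response, 7 more and 3 less in Bla-2. CYP94B3 (AT3G48520), which hydroxylates the active jasmonate conjugate, rose by 3.83 in Bla-2, and its change was 0.3 in Kon, a difference of 3.53 (SE 0.56) at adjusted p = 0.0111. On the 14 Kon arrays it lay between 3.89 and 4.88, and on the Bla-2 arrays between 4.04 and 8.14. CYP82G1 (AT3G25180), which makes a volatile homoterpene from geranyllinalool, rose by 2.6 in Kon, and its change was 0.08 in Bla-2, a difference of -2.52 (SE 0.29) at adjusted p = 0.000222. It lay between 3.58 and 4.29 on the Bla-2 arrays and between 3.57 and 6.71 on the Kon arrays. The response of 4 lists differed with the preset correlation and of 0 with an estimated one. Adjusted p with an estimated correlation was 0.359 for the MYC2 branch, with a median difference of -0.51, 0.359 for leaf volatiles at -0.55, 0.387 for auxin response and expansins at 0.29, and 0.904 for anthocyanin and flavonol genes at -0.24. Without Bla-2 feeding site replicate 1 the last median was 0.001. The number of genes was 4 without control replicate 1 of Bla-2, 6 without its control replicate 2, 4 without control replicate 1 of Kon and 17 without its control replicate 2, and 3 with dim probe sets left out.

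At 24 h 19 genes differed in response, 3 more and 16 less in Bla-2. AIG1 (AT1G33960), a gene induced by bacterial infection, rose by 4.32 in Kon, and its change was 0.1 in Bla-2, a difference of -4.22 (SE 0.41) at adjusted p = 1.78e-05. It stayed between 2.27 and 2.66 on all 14 Bla-2 arrays. A probe set that matches the transcript of 1 accession poorly can also stay low there, which was not tested for AIG1, CYP94B3 or CYP82G1. AT4G16260 differed by -3.1, PNP-A (AT2G18660) by -2.55 and TAT3 (AT2G24850) by -2.1, where TAT3 rose in both accessions, by 4.53 in Bla-2 and 6.63 in Kon. The number at 24 h was 7 without Bla-2 24 h replicate 1, 6 without either Bla-2 control array, 9 and 7 without Kon 24 h replicates 1 and 2, and 8 without Kon control replicate 2, and 8 with dim probe sets left out. The F-test over the 5 times called 61 genes that differed in response. Their number was 35 without Bla-2 control replicate 1, 31 without Bla-2 control replicate 2 and 39 without Kon 24 h replicate 2. It was 25 with dim probe sets left out and 40 without the 1 h arrays, a setting chosen after the data had been seen.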

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

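Of the tests here, those on heat shock genes, on the clock list and on the placement of the 12 h arrays on the other accession were chosen only after the results had been seen. The starvation test and the test of 12 h arrays against other groups were first written after the 12 h difference had been seen. Their own values were not yet known then. The bootstrap intervals of the starvation and clock lists were also added after their medians were known. They resampled the genes of a list, so they measure the spread between its genes and not between arrays.

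The interaction tests found genes whose response to mites differed between Bla-2 and Kon. There were 10 at the feeding site, 1 at 1 h, 3 at 3 h, 23 at 6 h, 45 at 12 h and 19 at 24 h, and 61 by the F-test over the time course, and each is given because the test of the difference itself passed its threshold. Chosen after its value was seen, the gene at 1 h was HSP17.6A (AT5G12030) with a difference of 1.44, and those at 3 h were MES5 (AT5G10300) at 1.47, AT3G53250 at 1.32 and AT3G28220 at -1.79. Leaving out single arrays gave 4 to 17 genes at the feeding site, 0 to 13 at 1 h, 0 to 4 at 3 h, 6 to 25 at 6 h, 14 to 28 at 12 h, 6 to 15 at 24 h and 31 to 68 by the F-test, where the lowest was reached without Bla-2 control replicate 1, except for the F-test, where it was reached without Bla-2 control replicate 2. At 12 h the count was 14 without the 2 deviating 12 h arrays. With renewed quantile normalization it was 0 at 1 h, and without dim probe sets 0 at 1 h, 6 at 6 h and 8 at 24 h. Poor matching of a probe set to 1 accession was not tested for these differences. At the feeding site the response was higher in Bla-2 for CYP94B3 (AT3G48520) by 3.53, AT4G20860 by 2.27, AT3G57460 by 1.99, PP2-A5 (AT1G65390) by 1.82, MES5 by 1.44 and ILR1 (AT3G02875) by 1.28. It was lower for CYP82G1 (AT3G25180) at -2.52, AT1G72940 at -1.92 and AT2G22200 at -1.75. At 24 h it was higher in Bla-2 for CYP86A1 (AT5G58860) by 1.29, MES5 by 1.25 and CRK15 (AT4G23230) by 1.21. It was lower for AIG1 (AT1G33960) at -4.22, AT4G16260 at -3.1, PNP-A (AT2G18660) at -2.55, TAT3 (AT2G24850) at -2.1, SAG29 (AT5G13170) at -1.81 and AT5G55450 at -1.8. In control plants the level in Bla-2 minus that in Kon was 2.35 for AT1G72940, 2.44 for AT5G55450, 1.54 for PNP-A and 1.26 for TAT3, genes with the smaller response in Bla-2. It was -0.28 for CYP82G1, -0.23 for AT2G22200, -0.24 for AIG1, -0.32 for AT4G16260 and 0.07 for SAG29.

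Differences between control plants may come from sequence under the probes. Of the 472 control differences of at least 2-fold, 71% had the same sign and were again at least 2-fold in the feeding site arrays. The explanation as written beforehand needed nearly all of them to do so, and only a share under 50% was set to count against it. A stable difference in expression predicts the same, so the explanations cannot be told apart without probe sequences or genomes of the accessions, which were not used here.

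Heat shock genes were higher at 1 h of 10 mites than in any other group. A response that grows with the number of mites predicts the feeding site at or above 1 h. The median difference of the list, feeding site minus 1 h, was -1.97 in Bla-2 and -1.63 in Kon. The pattern was picked with the feeding site already seen below 1 h, so this restates it. Any difference in handling at 1 h would also enter these values, so they do not decide on the number of mites. A difference in handling or temperature of the plants harvested for 1 h stays open. All 4 of the 1 h arrays had a list mean above every other array of their accession, and without a control of 1 h this cannot be told apart from the 1 h treatment itself. A response to few mites that is absent under many was not tested.

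The 12 h replicates differed within both accessions in a shared pattern. The difference of Bla-2 replicate 1 minus 2 and that of Kon replicate 2 minus 1 correlated at r = 0.55 across genes, led by AT3G15450, AT1G80440 and TPS11 (AT2G18700), named after their values were seen. A harvest at another time of day was taken to predict a common shift of clock genes beyond 0.5. The day and evening list moved by -0.25 in Bla-2, with a 95% bootstrap interval of -0.69 to -0.05. In Kon it moved by 0.17, with -0.23 to 0.31. The list joins clock genes of the day and of the evening, which another harvest time can move in opposite directions. Its median can then stay small, so the test cannot decide and this explanation stays open. Carbon starvation or dim light was not settled. The median of 14 starvation genes, listed without any gene seen among the leading ones, was 0.21 in Bla-2 and 0.59 in Kon. The median in Bla-2 lay under the bound of 0.5, so by that rule the explanation failed. The bound was set after the 12 h difference had been seen and before these medians. In Bla-2 the interval of 0.02 to 0.66, over the genes of the list, cannot overturn the rule, and in Kon it was 0.25 to 0.8. Of the 14 genes 11 were higher on the deviating array in both accessions. The list stood above 99.95% of 10000 random lists in Bla-2 and 100% in Kon. Genes of a pathway can move together, which random lists do not carry, so this does not settle the cause. With 1 array on each side of a difference the spread between arrays was not measured, so the explanation is not called excluded. A mislabelled array was neither shown nor excluded. The test for it was written after the 12 h difference had been seen, for a time replaced by another version, and then restored. In it 4 of the 4 arrays of 12 h were closer to the mean of another group of their accession than to their partner. The same held for 6 of the other 24 arrays, but this largely restates that the partners differ. Placed on the other accession, with its deviating 12 h array left out, 0 of the 2 deviating arrays were closest to 12 h, with r = 0.33 at 24 h against 0.27 at 12 h for Bla-2 replicate 1, and 0.41 at both 6 and 24 h against 0.33 for Kon replicate 2, margins too small to decide. Against another group of the series speak their positions on the fourth principal component, at -0.399 and -0.416 with all other arrays between -0.237 and 0.31, and their highest r with another group, 0.24 and 0.29. Neither excludes it, since that component follows the deviation itself and partners in other groups had r as low as 0.01. Of the 24 arrays with mites 22 were closest to their own condition in the other accession, although the 12 h reference there shares the deviation. A further test of this explanation ran on genes picked for the difference itself and was discarded as void.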

How the results depend on the processing

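The fits without the 1 h arrays, without the 2 deviating 12 h arrays and with crossed replicate numbers were chosen after the results were seen. All 20 main counts stayed within 1.5 times their value under renewed quantile normalization, centring, a trended and robust variance and the replicate block, where the feeding site counts were 2544 in Bla-2 and 1352 in Kon. With the numbers of 1 group crossed the block gave 848 at 1 h in Bla-2, 728 at 3 h in Kon and 40 for the accession difference at 12 h. Of 456 list tests, 107 lost their call with an estimated correlation. Averaging several probe sets of a gene did not apply, and signal over background was not computed. The order of the accessions turned with separate fits at 3, 6, 12 and 24 h, by the F-test, for feeding site against 1 h and for 24 h against 1 h. The call at 1 h for an accession difference in response was lost, with 0 genes, under the replicate block, renewed quantile normalization and without dim probe sets, and there were 5 with centring and with the trended variance. At 24 h there were 12 with the replicate block and 8 without dim probe sets, in place of 19, and at 6 h 6 without dim probe sets, in place of 23.

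Requiring at least 2-fold, which by construction keeps fewer genes, gave in Bla-2 and Kon 329 and 312 at 1 h, 260 and 289 at 3 h, 422 and 449 at 6 h, 294 and 540 at 12 h, 299 and 435 at 24 h, 565 and 539 at the feeding site, 82 and 130 for feeding site against 1 h, and 603 and 739 by the F-test. It gave 472 for control plants and 408 shared feeding site calls. Fitted apart, Kon had 450 at 1 h, 440 at 3 h, 817 at 6 h, 1471 at 12 h, 1047 at 24 h and 1228 by the F-test. Bla-2 had 1877 at 12 h, 2567 at 24 h, 336 for feeding site against 1 h and 2747 by the F-test. Separate fits keep the fold changes within an accession and change only the estimate of the spread and its degrees of freedom. The SD of the replicate difference in Bla-2 and Kon was 0.151 and 0.206 in control plants, 0.254 and 0.303 at 1 h, and 0.162 and 0.292 at 3 h. It was 0.175 and 0.298 at 6 h, 0.278 and 0.293 at 12 h, and 0.18 and 0.22 at 24 h. At the feeding site it was higher in Bla-2, at 0.268 and 0.221. Without dim probe sets, so with fewer genes tested, there were 1136 for control plants, 121 for feeding site against 1 h in Bla-2, and 3 and 25 for the accession differences at the feeding site and over the time course. The last was 40 without the 1 h arrays, and 12 h in Bla-2 was 613 without the deviating arrays, where the cause was not tested.

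Leaving out single arrays, with the remaining array of a group assumed to vary like the other groups, gave these lowest and highest counts: 307 to 1189 and 325 to 1491 at 1 h in Bla-2 and Kon, 239 to 319 and 330 to 755 at 3 h, 637 to 721 and 713 to 1372 at 6 h, 357 to 832 and 1185 to 1857 at 12 h, and 406 to 804 and 753 to 1131 at 24 h. They were 1046 to 2546 and 763 to 1143 at the feeding site, 28 to 350 and 68 to 256 for feeding site against 1 h, 991 to 1939 and 1835 to 3509 by the F-test, 896 to 1117 for control plants, 633 to 994 for shared calls, and 4 to 17 and 31 to 68 for the accession differences at the feeding site and over the time course. The anthocyanin and flavonol list's median accession difference of -0.24 ranged from -0.44 without Bla-2 feeding site replicate 2 to 0.001 without replicate 1, and the cause was not tested.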

Other observations

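The comparison of 24 h with 1 h, its list tests and the count of genes higher in all conditions were chosen only after the results had been seen. Between 1 h and 24 h of 10 mites 893 genes differed in Bla-2 and 1111 in Kon. With the accessions fitted apart the order turned, with 1408 in Bla-2 and 517 in Kon. Without 1 h replicates 1 and 2 and 24 h replicates 1 and 2 in turn there were 397, 505, 324 and 277 in Bla-2, and without Kon 1 h replicate 2 and 24 h replicates 1 and 2 there were 721, 427 and 567 in Kon. The salicylate list rose between these times in both accessions, for 6 of 15 genes in Bla-2 and 10 in Kon. The median difference was 0.76 in Bla-2 and 1.13 in Kon, with adjusted p = 0.0293 and 0.0134 with an estimated correlation. The list was chosen because it had been seen higher late, so this test restates that observation and supports no explanation. JAZ and turnover genes were lower at 24 h than at 1 h for 10 of 20 genes in Bla-2 and 1 in Kon, with 1 higher in each, and the list's adjusted p with an estimated correlation was 0.155 and 0.833. Its mean on the Bla-2 arrays was 8.05 and 7.56 at 1 h and 7.39 and 6.83 at 24 h. In Kon it was 7.23 on both arrays at 1 h and 7.07 and 7.04 at 24 h. Whether the accessions differ in this comparison was not tested.

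A set of 137 genes was higher in all 6 conditions with mites in both accessions, from 189 in Bla-2 and 219 in Kon. The comparisons within an accession share their control arrays, and how far this raises these numbers was not measured. Of the 137, 12 belonged to the 20 measured JAZ and turnover genes, 6 to jasmonate biosynthesis and 6 to indole glucosinolates.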
